A study of Mus musculus with 6 samples.

How the data were processed

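The series holds 6 2-colour hybridisations of mouse hypothalamus RNA on oligonucleotide arrays printed by the submitters, per the labels. Mice of the collagen group received 100 µl of type II collagen in 100 µl of complete Freund's adjuvant and control mice 200 µl of the adjuvant, both received lipopolysaccharide on day 24, and total RNA was taken with TRIzol. The time of death is given in the labels as day 31 with an unclear unit. The labels describe 3 biological replicates, each with 2 technical replicates in a dye swap. The pair of extracts was therefore the replicate, and its 2 arrays were averaged first. The pairing comes from this design, since both members of a pair were hybridised together on the same arrays, and the agreement of same-numbered arrays stands in the results.

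The deposited scanner files, 2 or 3 repeat scans per array and 16 in all, give for each spot an intensity in channel A and in channel B, already corrected for local background by the authors, per the file headers, together with the background and the spot area in pixels. The scanning software and any genome build are not given in the sources used here. A channel that was flagged as not detected holds 0, and such values, with the few below 0, were treated as missing. The deposited series matrix holds a score per probe and array, made by the authors, with no scale stated. Set against the scanner files, the scores follow log2 of channel B over channel A on arrays with collagen RNA in Cy5 and its negative on those with collagen RNA in Cy3. The correlation was 0.67 to 0.85 in size with loess over the whole array and 0.80 to 0.92 with loess per print block, so the scores run in the same direction on all arrays. Their medians per array were -0.00232, -0.00257 and -0.00262 for pairs 1, 2 and 3 with collagen RNA in Cy5, and -0.00322, 0.00423 and -0.00352 with collagen RNA in Cy3, so each array is centred on 0. Their log base stays unknown, since their slope on log2 ratios was 0.50 to 0.63. The rows of the series matrix were matched to spots in print block order, which these correlations bear out, against -0.03 to 0.03 in file order.

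The intensities were used as deposited. A normexp background correction with offset 50 had been chosen before the data were examined, but the intensities were already background-subtracted, so normexp on foreground values rebuilt from intensity and background became an alternative. For each scan log2 of channel B over channel A was normalised by loess over the whole array (span 0.3), scans of 1 array were averaged, ratios were turned to collagen over control, and the 2 arrays of a pair were averaged, which cancels a dye effect equal on both. Both arrays had to give a ratio. No control spots are marked in the files, so none were left out. Probes with a mean log2 of foreground over background of at least 0.5 and values in at least 2 pairs were tested, which left 6547 of 10080. The test was limma 3.58.1 in R 4.3.3 (lmFit with an intercept, then eBayes), with Benjamini-Hochberg adjustment and a threshold of 0.05. P-values and standard errors of single probes rest on the spread between pairs of extracts, moderated by eBayes toward the spread of all probes. That prior carried 4.82 degrees of freedom, against 2 of a probe's own when measured in 3 pairs. They therefore do not measure the spread of a probe's own pairs alone. Figures were drawn with matplotlib.

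Gene names came from the platform annotation supplied with the series matrix, updated through Entrez gene numbers in a RefSeq gene table of assembly GRCm38.p6, which was used for names only. Of 9078 annotated probes, 8977 matched by that number, 12 listed several genes and were not named, and 1014 of 10080 probes had no name here. A gene with several probes is given by its brightest.

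The 28 gene and cell type lists and the rule for named genes were fixed before the data were examined. The rule takes up to 12 genes per direction by size among those past the adjusted test with 1 sign in all pairs, filled from those with an unadjusted p under 0.05 and 1 sign on all 6 arrays, then up to 4 members of each list by unadjusted p, and the genes Crh, Avp, Oxt, Pomc, Trh, Npy, Nr3c1, Il1b, Il6, Tnf, Gfap and Ttr. Of these Crh, Pomc, Npy, Nr3c1, Tnf, Gfap and Ttr were not found among the annotated probes. The results name a part of the resulting 106 genes. Lists with at least 3 tested genes were tested by limma's camera on the moderated statistics with a preset correlation of 0.01, in its form for preranked statistics, since missing pairs rule out the form on expression values. Camera with estimated correlation and fry were run on the probes with all 3 pairs. With an estimated correlation camera takes its degrees of freedom from the pairs, so it had little power here.

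The procedure was tested on simulated data for the comparison of collagen against control, with 6547 probes, 200 of them changed. Noise was drawn independently for each array, from each probe's spread over the 6 arrays around its dye and collagen terms. No part of the noise was shared by the 2 arrays of a pair. It called 2 of 62 probes changed by 0.5 log2 units, 30 of 73 changed by 1, 60 of 65 changed by 2, and 1 unchanged probe. Alternatives covered the background, the normalisation, the filter, the scans, each pair left out, the 6 arrays with a dye term with and without the pair as a replicate block, each dye orientation alone, the authors' scores, and 4 settings chosen after seeing the data. Plain background subtraction equals the main setting.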

Results

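Gene expression was measured in the hypothalamus of male C57Bl/6 mice, an inbred laboratory strain, that had received type II collagen in complete Freund's adjuvant at 8 weeks of age, and in mice of the same age that had received the adjuvant without collagen. Collagen in adjuvant is the standard way of inducing an autoimmune arthritis in mice, and complete Freund's adjuvant is a mineral oil emulsion with killed mycobacteria. Both groups were given bacterial lipopolysaccharide on day 24. The question was which hypothalamic transcripts differ between collagen and control mice. Whether the collagen mice had arthritis was not measured here. RNA from 3 collagen mice or groups of mice was set directly against RNA from 3 adjuvant controls on printed oligonucleotide arrays with 2 dyes. Each of the 3 pairs of extracts was hybridised to 2 arrays with the dyes exchanged, which gave 6 arrays and n = 3 pairs for every comparison. The labels do not say whether an extract came from 1 animal or from several. Each array carried 10080 spots. Between 4720 and 9022 spots per scan, or 46.8% to 89.5%, had signal in both channels. Among these spots alone, the foreground of the median spot was 1.72 to 6.23 times its local background. The arrays with collagen RNA in Cy3 gave a ratio for 6170, 8455 and 5232 probes in pairs 1, 2 and 3, against 9463, 9895 and 9384 for those with collagen RNA in Cy5. A probe was tested where at least 2 pairs had it on both arrays, which left 6547 probes, 3920 of them in 3 pairs, for 5827 named genes. Depth in reads does not apply to arrays, and the number of arrays limits the precision.

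No transcript passed the test between collagen and control mice. The limma test with Benjamini-Hochberg adjustment called 0 of 6547 probes at 0.05, and the lowest adjusted p was 0.9995. The highest ratios among genes with an unadjusted p under 0.05 and 1 sign on all 6 arrays belonged to Gps1, a subunit of the COP9 signalosome, Psd, an exchange factor for Arf6 at synapses, Bcs1l, an assembly factor of respiratory complex III, and Smox, spermine oxidase. Their mean log2 ratios of collagen over control were 1.03 ± 0.32, 0.45 ± 0.13, 0.45 ± 0.11 and 0.43 ± 0.11 (SE, n = 3 pairs). Each SE given with a ratio is limma's moderated one, which draws on the spread of all probes. For genes whose pairs differ widely it is smaller than the spread of their own pairs would give. The Gps1 value came largely from pair 1, at 2.12 against 0.31 and 0.66 in pairs 2 and 3. Dctn2, the dynamitin subunit of dynactin, stood at 0.42 ± 0.15, Rundc3a at 0.35 ± 0.12, Btbd17 at 0.34 ± 0.14, and Ipo4, a nuclear import receptor, at 0.32 ± 0.12 (SE, n = 3 pairs). Fxyd1, a regulator of the sodium pump, was at 0.32 ± 0.11, the forkhead factor Foxp4 at 0.31 ± 0.11, and Phlpp1, a phosphatase of Akt, at 0.27 ± 0.11 (SE, n = 3 pairs). Under the same rule 3 genes lay below 0. Hes5, a transcription factor induced by Notch, stood at -0.45 ± 0.13, Atad1, an ATPase of the outer mitochondrial membrane, at -0.33 ± 0.12, and Acadsb, a mitochondrial acyl-CoA dehydrogenase for branched chains, at -0.29 ± 0.11 (SE, n = 3 pairs). None of these 14 genes passed the adjusted test.

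**Figure D1:**
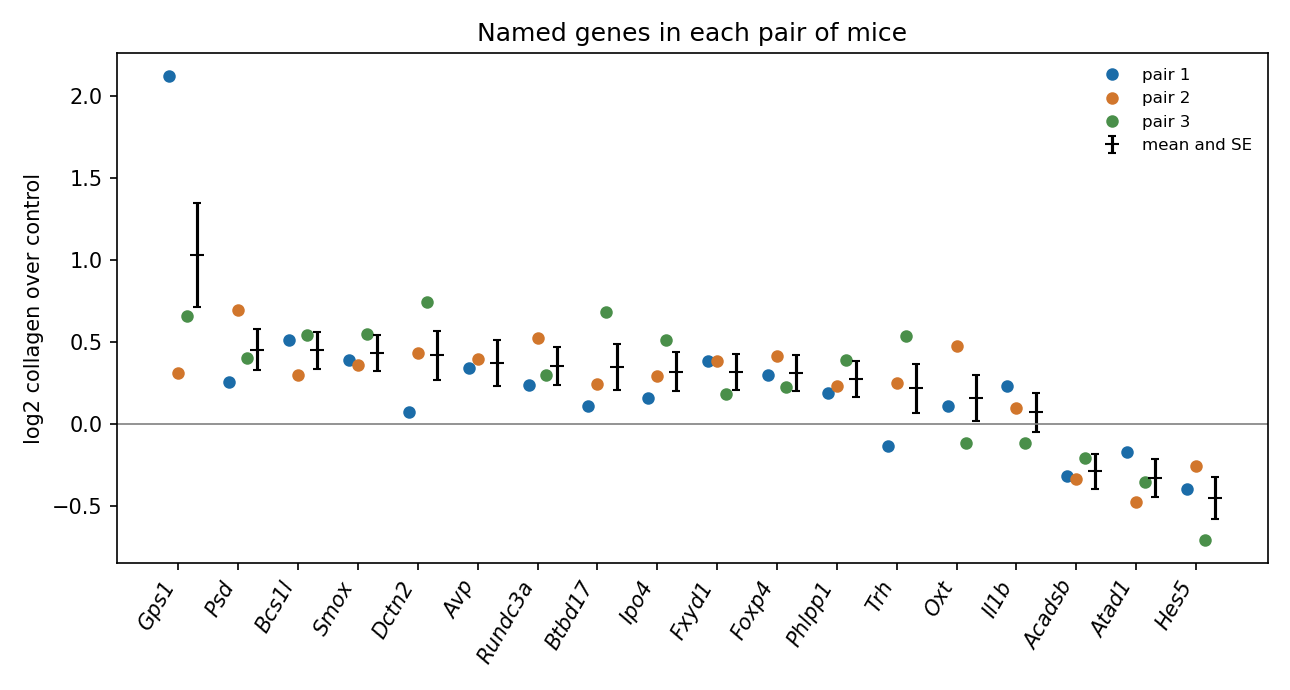
Log2 ratio of collagen over control (vertical axis) for the genes chosen by size and for 4 genes named in advance, with 1 point per pair of mice and the mean and limma's moderated standard error in black. Gps1 reaches 2.12 in pair 1 and 0.31 in pair 2, while the other genes lie within 1 log2 unit of 0 in every pair.

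The direction of these ratios is likely, not settled. The scanner files call the channels A and B without naming the dyes. Channel A was taken as Cy3 because the labels list Cy3 first, and because the authors' processed values then run as collagen over control on all 6 arrays, which is the comparison the design names. With the opposite assignment the sign of every collagen over control ratio would turn.

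Fewer probes had an unadjusted p under 0.05 than chance alone would give, with 135 found and 327.35 expected among 6547. Of these, 74 were higher and 61 lower in collagen mice. Without pair 2 the count exceeded the expected one, at 315 of 4102 against 205.1. Without pair 1 it was 131 against 238, and without pair 3 it was 77 against 276.2. It also exceeded the expected one with collagen in Cy5 alone, at 588 against 485.2, and in Cy3 alone, at 494 against 332. Median centring in place of loess gave 147 higher and 9 lower, and called 10 probes after adjustment. The median standard error of a log2 ratio was 0.139, and the 95% confidence interval excluded a 2-fold change for 99.0% of the tested probes, each taken alone. In simulated data the same test recovered 3.23% of probes changed by 0.5 log2 units. It recovered 41.1% of those changed by 1 and 92.3% of those changed by 2. The simulated noise had the spread of single arrays, not of pairs. It put 5.26% of unchanged probes at an unadjusted p under 0.05 by limma, against 135 of 6547 probes in the real data. The recovered shares may therefore not hold for the real pairs. The sign was the same on all 6 arrays for 65 of 3920 probes, or 1.66%, where chance would give 3.125% for independent arrays. The 2 arrays of a pair were not independent, since their ratios correlated at -0.49 to -0.33. The share that chance gives for these arrays is therefore not 3.125%.

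Hypothalamic hormones and their receptors gave no list past the adjusted test. Among 15 neuropeptide genes, 9 lay above 0 and 6 below, with a median log2 ratio of 0.04. Avp, the precursor of vasopressin, stood at 0.37 ± 0.14 (SE, n = 2 pairs), Gnrh1, the precursor of the gonadotropin-releasing hormone, at 0.21 ± 0.11, Trh, the precursor of the thyrotropin-releasing hormone, at 0.21 ± 0.15, and Oxt, the precursor of oxytocin, at 0.15 ± 0.14 (SE, n = 3 pairs). Pmch, the precursor of melanin-concentrating hormone, was at -0.19 ± 0.14 (SE, n = 2 pairs). Trh stood below 0 in the authors' processed values, and Oxt both there and without pair 2. The genes of Crh, Pomc, Npy and Nr3c1 were not measured here. Of 9 receptors of energy balance and prohormone processing enzymes, 6 lay below 0, with a median of -0.08. Mc4r and Mc3r, melanocortin receptors of energy balance, stood at -0.43 ± 0.19 (SE, n = 3 pairs) and -0.32 ± 0.14 (SE, n = 2 pairs). The Mc4r value came largely from pair 2, at -0.98 against -0.06 and -0.25 in pairs 1 and 3. This list had an unadjusted p of 0.041 and an adjusted p of 0.289 by limma's camera test, and its median turned to 0.05 without pair 2 and to 0.04 with collagen in Cy3 alone, where 7 genes lay above 0 and Mc3r stood at 0.11. Of 11 genes of the stress axis and the glucocorticoid response, 5 lay above 0 and 6 below. Klf9, a target of glucocorticoid and thyroid hormone, stood at 0.23 ± 0.12, and Fkbp5, a glucocorticoid target, at -0.10 ± 0.12 (SE, n = 3 pairs). In the thyroid axis 3 of 5 genes lay above 0, with an adjusted p of 0.735 by camera.

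No inflammatory transcript passed the test. Of 16 cytokine, chemokine and inflammatory signalling genes, 10 were above 0, with a median of 0.05 and an adjusted p of 0.917 by camera. Without pair 1 this list had 5 genes above 0 and 6 below, with a median of -0.0128, and with collagen in Cy5 alone 12 above and 14 below. With median centring 13 of the 16 lay above 0, with a median of 0.23, an unadjusted p of 0.0322 and an adjusted p of 0.177 by camera, and with normexp 11 of 16, with a median of 0.14. Il1r2, a decoy receptor for interleukin 1, stood at 0.26 ± 0.15, Socs3, a feedback inhibitor of cytokine signalling, at 0.22 ± 0.14, and Lcn2, an acute phase protein, at 0.23 ± 0.14 (SE, n = 2 pairs). Il1b, the gene of interleukin 1 beta, stood at 0.07 ± 0.12 (SE, n = 3 pairs), and it turned below 0 with normexp and without pair 1. Il6 was on the array without enough measured pairs for a test, and Tnf was not measured here. Of 8 interferon response genes 7 lay above 0, with a median of 0.19, an unadjusted p of 0.0254 and an adjusted p of 0.289 by camera. Without pair 1 the median over these 8 genes was 0.078, and over the genes still in 2 pairs it was 0.13 without pair 1 (4 genes) and 0.37 without pair 2 (3 genes). Mx1, an antiviral GTPase, stood at 0.30 ± 0.17, Irgm1 and Gbp2, both GTPases induced by interferon gamma, at 0.23 ± 0.14 and 0.22 ± 0.11 (SE, n = 3 pairs), and Rsad2, the antiviral enzyme viperin, at -0.36 ± 0.15 (SE, n = 2 pairs). The Mx1 value came largely from pair 1, at 0.77 against 0.15 and -0.03 in pairs 2 and 3. The interferon list passed with a stricter filter on dim probes, at an adjusted p of 0.0454 over 5 genes, and with the first scan of each array alone, at 0.00371 over 6 genes. An estimated correlation between its 3 genes measured in all pairs gave adjusted p-values by camera of 0.963 with the stricter filter and 0.828 with the first scan. Without either change it gave 0.966. With the preset correlation on 3 genes the values were 0.0598, 0.0183 and 0.0635 by camera. With 3 pairs the estimated correlation has little power and does not settle the calls. All 4 complement genes lay above 0, with a median of 0.21 and an adjusted p of 0.305 by camera. Without pair 1 the complement median was -0.0175 over 2 genes, and with the 6 arrays and a dye term it was 0.0995. Among them C1qc stood at 0.30 ± 0.16 and C1qa at 0.29 ± 0.22 (SE, n = 2 pairs), the latter with a different sign in each pair. Antigen presentation was represented by Cd74, the invariant chain, alone, at 0.13 ± 0.19 (SE, n = 2 pairs).

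All 6 immediate early genes, which neurons transcribe within minutes of stimulation, lay above 0, with a median of 0.17, an unadjusted p of 0.0387 and an adjusted p of 0.289 by camera. The pairs differed in sign. Fos stood at 0.43, -0.69 and 0.71 in pairs 1, 2 and 3, Fosb at 0.34, -0.51 and 0.38, and Nr4a3 at 0.41, -0.56 and 0.69. Jund went another way, at 0.50, 0.56 and -0.17, while Nr4a2 stood at -0.31 and 0.37 in pairs 1 and 2 and Fosl2 at 0.23 and 0.34 in pairs 2 and 3. The means were 0.30 ± 0.16 for Jund (SE, n = 3 pairs) and 0.29 ± 0.14 for Fosl2 (SE, n = 2 pairs). The dye orientations differed as well. With collagen in Cy5 alone Nr4a3 stood at -1.40, Fos at -0.56 and Fosl2 at -0.03, while Jund kept its sign. With collagen in Cy3 alone Nr4a3 stood at 1.76. Without pair 2 the list passed the test, with a median of 0.46 over 4 genes and an adjusted p of 0.0024 with the preset correlation. With an estimated correlation, which came out at 0, the adjusted p without pair 2 was 0.966 by camera, and by fry it was 0.0596. As the estimate was 0, correlation between the genes does not account for the higher p. Without pair 3 the median was -0.07.

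Neurotransmission, clock and housekeeping lists had adjusted p-values of 0.592 or more by camera. Of 12 glutamate and GABA genes 5 lay above 0 and 7 below, among them Gad2, which makes GABA, at -0.39 ± 0.14 (SE, n = 2 pairs), Gabrb2, a subunit of the GABA-A receptor, at -0.26 ± 0.19 (SE, n = 2 pairs) and Slc32a1, the vesicular GABA transporter, at 0.21 ± 0.16 (SE, n = 3 pairs). Gabrb2 turned to 0.16 with collagen in Cy3 alone. Of 9 monoamine and opioid genes 4 lay above 0, with Ddc, an enzyme of dopamine and serotonin synthesis, at 0.29 ± 0.16 and the serotonin transporter gene Slc6a4 at 0.16 ± 0.13 (SE, n = 3 pairs). Both came largely from pair 1, Ddc from 0.75 against 0.08 and 0.03 in pairs 2 and 3 and Slc6a4 from 0.42 against 0.08 and -0.02, and Ddc stood at -0.08 with collagen in Cy5 alone. The clock genes were divided, 5 above and 4 below 0, with Cry1 at -0.27 ± 0.20 (SE, n = 3 pairs), from -0.81, 0.29 and -0.30 in pairs 1, 2 and 3, and Per3 at 0.19 ± 0.16 (SE, n = 2 pairs). Of 9 chaperone and unfolded protein response genes 7 lay above 0, with Dnajb1, a heat shock cochaperone, at 0.26 ± 0.12 (SE, n = 3 pairs). The 22 oxidative phosphorylation genes and the 27 cytosolic ribosomal protein genes had medians of 0.0047 and -0.0048, with 12 above 0 in each list. With median centring the ribosomal list had 8 genes above 0 and 19 below, at an adjusted p of 0.0723 by camera. With foreground values it had 18 above and 9 below.

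Markers of cell types near or within the hypothalamus gave no call either. The 13 neuronal and synaptic genes had a median of 0.03, with Snap25, a synaptic vesicle fusion protein, at -0.29 ± 0.11 and Syn1, a vesicle coat protein, at 0.27 ± 0.15 (SE, n = 3 pairs). Snap25 lay below 0 on 3 of the 6 arrays only, and stood at 0.25 with collagen in Cy3 alone. The 6 microglia and macrophage genes were evenly divided around a median of -0.0022. P2ry12, a receptor of resting microglia, stood at -0.25 ± 0.11 and Laptm5 at 0.26 ± 0.14 (SE, n = 3 pairs). P2ry12 lay below 0 on 3 of the 6 arrays only, and Laptm5 was just below 0 with the first scan alone. Medians were 0.03 for 4 astrocyte genes, 0.04 for 6 oligodendrocyte genes, 0.12 for 4 endothelial genes, 0.01 for 4 genes of the anterior pituitary and 0.01 for 5 genes of thalamus and cortex. Meningeal and fibroblast genes lay lower, with 3 of 4 below 0, a median of -0.14 and an adjusted p of 0.289 by camera. Among them Igf2 stood at -0.27 ± 0.12 and Dcn at -0.20 ± 0.11 (SE, n = 3 pairs), and the median turned above 0 with normexp and with median centring. Lists with fewer than 3 measured genes were not tested. The T cell marker Ccr7 stood at 1.04 ± 0.46 (SE, n = 2 pairs), from 2.09 in pair 1 and -0.01 in pair 2. The moderated SE understates the spread of these pairs, whose standard deviation was 1.48. The neutrophil genes Lcn2 and Elane stood at 0.23 ± 0.14 and 0.18 ± 0.15 (SE, n = 2 pairs), the B cell gene Cd79a at 0.01 ± 0.16 and the choroid plexus gene Kl at 0.02 ± 0.11 (SE, n = 3 pairs). None of the red blood cell genes was among the annotated probes. In all, 22 of 28 lists were tested, 3 had an unadjusted p under 0.05 and 0 passed, and 0 of 210 list genes passed, whether adjusted over all probes or adjusted over the list alone.

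**Figure D2:**
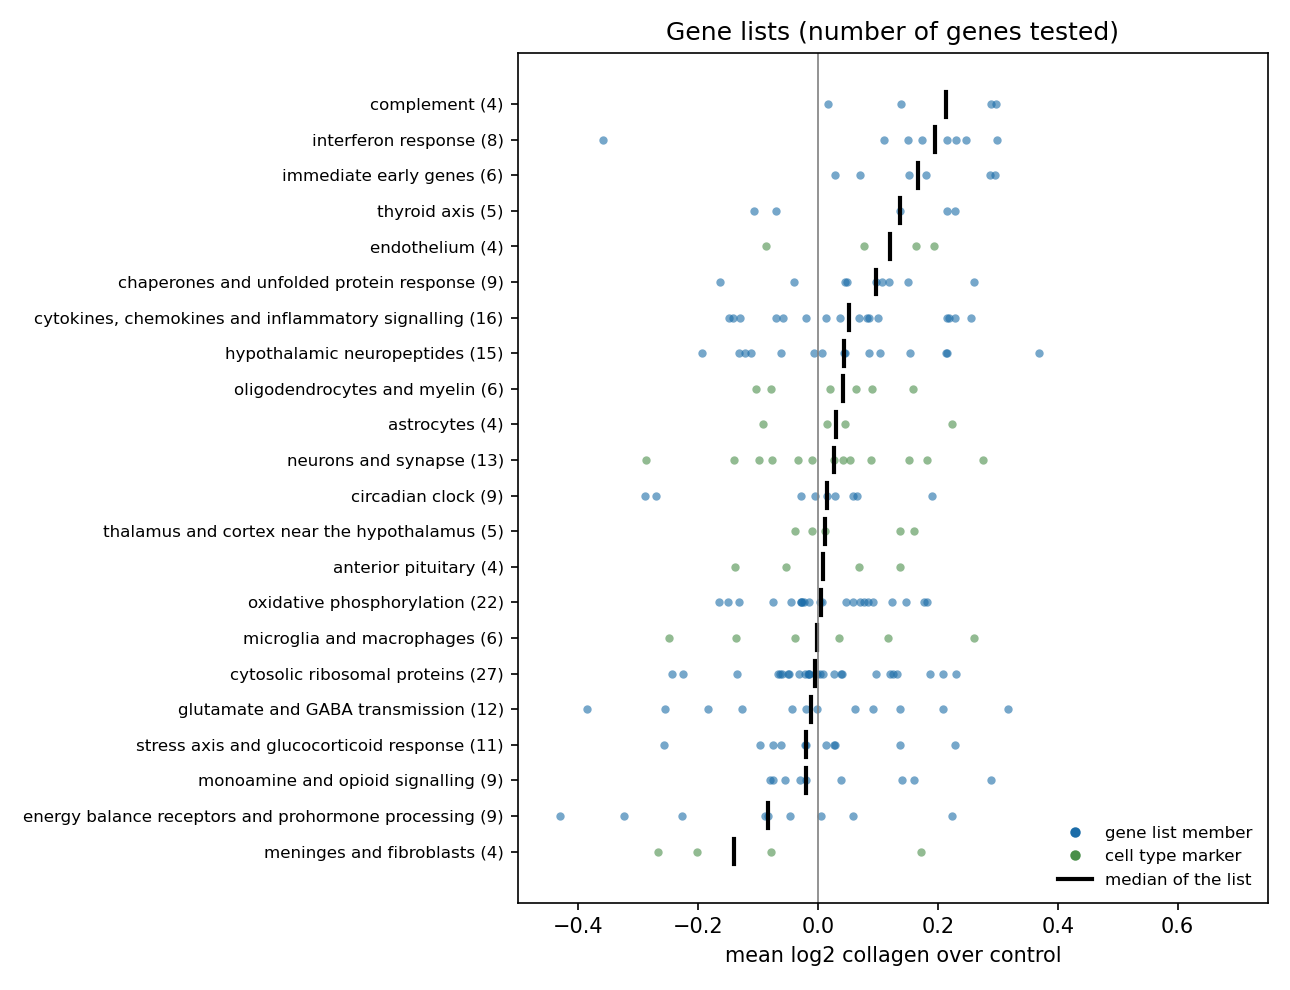
Mean log2 ratio of collagen over control (horizontal axis) of each tested member of 22 gene lists, with the number of genes tested in brackets and the list median as a black bar. The highest median is 0.21 for complement and the lowest is -0.14 for meninges and fibroblasts, and no list passed the adjusted test.

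The log ratios of the pairs did not go together. Across probes, which are not independent replicates, pair means of log2 collagen over control correlated at r = -0.16 between pairs 1 and 2, 0.16 between pairs 1 and 3 and -0.17 between pairs 2 and 3. The 2 arrays of a pair, which carried the same extracts with the dyes exchanged, correlated at -0.33, -0.49 and -0.34 in pairs 1, 2 and 3. Before the ratios were turned to collagen over control, log2 of channel B over channel A correlated at a mean of 0.26 between arrays of different pairs with opposite dyes and at 0.23 between those with the same dyes. A limma fit to the 6 arrays with a dye term found 68 probes with a dye difference past an adjusted p of 0.05, all brighter in channel A. Hyls1 and Dbf4 were among the named ones, at log2 ratios of A over B of 2.22 ± 0.14 and 2.13 ± 0.15 (SE), and 32 had no gene name here, which takes in any control spots, since the files do not mark them. The collagen term of that fit called 0 probes after adjustment and 159 at an unadjusted p under 0.05.

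**Figure D3:**
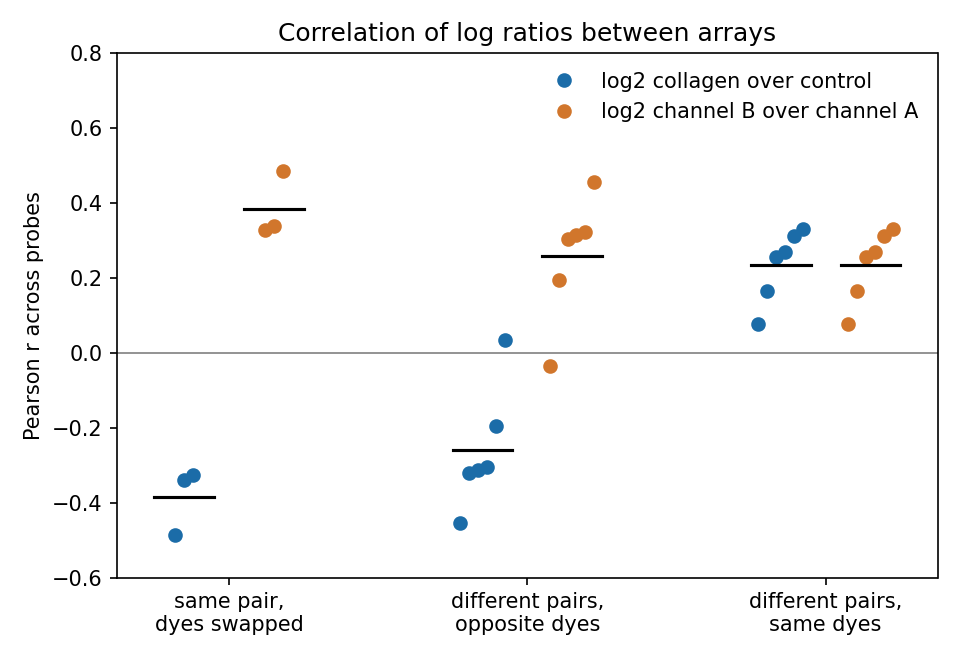
Pearson correlation across probes (vertical axis) between arrays of the same pair or of different pairs, for log2 collagen over control in blue and log2 channel B over channel A in orange, with 1 point per pair of arrays and black bars at the means. The collagen over control ratios of dye-swapped arrays of a pair lie at -0.49 to -0.33, below 0 in all 3 pairs.

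The largest ratios sat in a corner of the print order. Of 24 probes with a mean log2 ratio beyond 1 in size, 22 lay in the last 2 of 48 print blocks, which held 5.06% of the tested probes, and all 22 were higher in collagen mice. Their median log2 ratio was 5.31 on the array of pair 1 with collagen RNA in Cy3 and -0.03 on its dye-swapped partner. Among the genes named above, Gps1, Ccr7, Ipo4, Fxyd1 and Elane have their probes in these blocks. Without those blocks the test called 0 of 6216 probes after adjustment and 137 at an unadjusted p under 0.05.

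**Figure D4:**
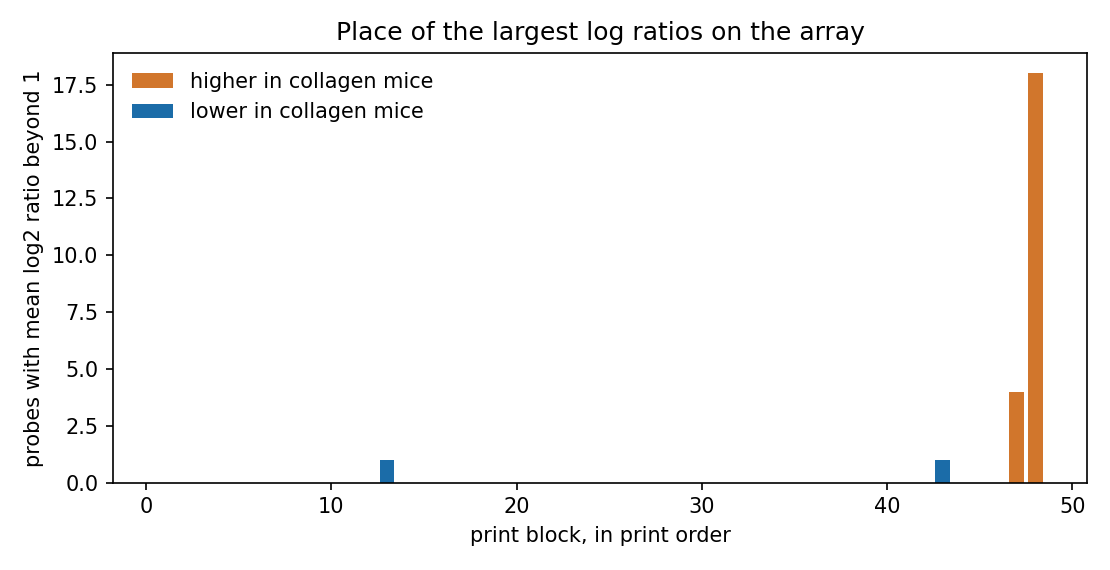
Number of tested probes with a mean log2 ratio of collagen over control beyond 1 in size (vertical axis) in each of 48 print blocks (horizontal axis), higher in orange and lower in blue. Blocks 47 and 48 hold 4 and 18 such probes, and blocks 13 and 43 hold 1 each.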

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

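The test of the dye effect across arrays in the weighing below was chosen after the result was seen.

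The contrast of collagen over control differed between the 2 dye orientations for 68 probes at an adjusted p under 0.05 by limma. All 68 were brighter in channel A, with a median log2 ratio of A over B of 1.81, and 32 of them, or 47.1%, had no gene name here against 8.54% of all tested probes (Fisher's exact test, two-sided, p = 3.71e-17). The files do not mark control spots, so the probes without a name take in any controls, and the share says nothing about genes. Named ones include Krt14, a keratin of skin, at 2.50, and Hyls1 at 2.22. With median centring 158 probes were called, 63 of them shared with loess, and with loess per print block 66, of which 58 were shared, and none of these was brighter in channel B.

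A wider pattern goes with it. The collagen over control ratios of the 2 arrays of a pair correlated negatively, at a mean r of -0.38, although both arrays carried the same extracts. Dim spots near background are argued against, since the mean correlation over the brightest 25% of probes was -0.57 and lay below 0 in all 3 pairs. A dye effect specific to each probe may account for the pattern, since log2 of channel B over channel A correlated at a mean of 0.26 between arrays of different pairs and opposite dyes, as high as the 0.23 between arrays with the same dyes. It stays open whether 1 array of each pair was not exchanged as its label says. The labelled pairing had the highest mean correlation of the 6 possible ones (rank 1, at 0.38 against 0.37 for the next), but with 6 pairings that rank alone cannot decide. Both arrays of a pair hold the same extracts, so no biological explanation was tested.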

How the results depend on the processing

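4 settings (only probes in all 3 pairs, loess per print block with the stricter filter, the brightest 25% of probes, and the last 2 print blocks left out) were chosen after seeing the data. The count of probes past an adjusted p of 0.05 by limma, 0 in the results, was also 0 with foreground values, normexp, loess per print block, scaling between arrays, both other filters on dim probes, the first scan alone, the authors' scores, collagen in Cy5 alone, a threshold of 0.1, and z-scores beyond 2 in all 3 pairs. It was 10 with median centring, 9 of them in the last 2 print blocks, 94 with collagen in Cy3 alone, 57 of them among the probes with a dye difference, and 1 with z-scores beyond 1.5 in all 3 pairs, where chance gives 1.34. Leaving out each pair gave 0 to 1, the 1 being Syn3 without replicate 1. Pairing enters through the pair means, and the 6 arrays with a dye term and the pair as a replicate block gave 0 probes after adjustment and 159 at an unadjusted p under 0.05, and without the block 0 and 145, so the block changed no call. The 135 probes at an unadjusted p under 0.05 became 205 with scaling between arrays, 588 with collagen in Cy5 alone and 494 with collagen in Cy3 alone, and ranged from 77 to 315 over the pairs left out, the highest without replicate 2 and the lowest without replicate 3. Each of those single orientations keeps the dye effect in the ratio by construction. For the other changes the cause was not tested.

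The mean correlation within pairs, -0.38, stayed below 0 in every pair and setting run, at -0.30 with normexp, -0.20 with median centring, -0.48 in the authors' scores and -0.57 in the brightest 25% of probes. No list passed in the results. With the stricter filter, with that filter and loess per print block, and with the first scan alone 1 list passed, the interferon response, at adjusted p-values by camera of 0.0454, 0.011 and 0.00371 (0.963, 0.942 and 0.828 with an estimated correlation), where its adjusted p in the other settings went up to 0.847. On the 3 genes behind each of those bracketed values, the preset correlation gave 0.0598, 0.0315 and 0.0183 by camera. With collagen in Cy3 alone 1 list passed, the immediate early genes at 0.00235 (0.989 with an estimated correlation). Leaving out each pair gave 0 to 1, the 1 being the same list without replicate 2 (0.966 with an estimated correlation). By fry the adjusted p of that list was 0.198 with collagen in Cy3 alone and 0.0596 without replicate 2. With so few pairs the estimated correlation does not settle these calls. Of 374 list medians outside the single orientations 74 changed sign, and interferon response, chaperones and endothelium were the 3 of 22 tested lists without such a change. Of 1631 values of the 106 named genes 80 changed sign, none among the 14 genes chosen by size. Those 14 had been picked for 1 sign on all 6 arrays, so leaving out a pair or adding a dye term could not turn them. Plain background subtraction was not run apart, since the deposited intensities hold it. Spots without signal in both channels limit the arrays with collagen in Cy3, which had as few as 46.8% of spots. Over the spots with signal in both channels, their median foreground over background was 2.18 to 6.23, against 1.72 to 3.34 with collagen in Cy5. These medians leave out the undetected spots, so they do not compare the same spots. The cause of the low detection was not tested.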

Other observations

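The tests of a local defect, of a difference between mice of 1 pair and of microglial RNA were chosen after the results were seen. Some genes outside the fixed rule, picked after their values were seen, stood apart. Syn3, a synapsin of vesicles, had a log2 ratio of collagen over control of 0.68 ± 0.23 (SE, n = 3 pairs), from 0.10, 0.52 and 1.41 in pairs 1, 2 and 3, and it passed limma's test without replicate 1, at an adjusted p of 0.00471. With 2 pairs left, at 0.52 and 1.41, limma's eBayes step draws on the spread of all probes. That p-value therefore does not measure the spread of Syn3 alone. Cldnd1, a claudin-like membrane protein, was the 1 gene beyond 1.5 local standard deviations in all 3 pairs, at -0.27, -0.60 and -0.46, where chance gives 1.34 such probes. Outside the last 2 print blocks, only Hsd17b4, a peroxisomal enzyme of fatty acid oxidation, and Gorasp1, a Golgi stacking protein, had a mean log2 ratio beyond 1 in size. Each rested on 1 array, Hsd17b4 on a value of -4.49 and Gorasp1 on one of -4.25.

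The largest log ratios crowded in the last 2 print blocks, with 22 of 24 probes, among them Cdk6, a cell cycle kinase, at a mean of 2.03, Kti12 at 1.77 and Gps1 at 1.03. A difference between the mice of pair 1 is argued against, since the median over the 22 probes was 5.31 on its array with collagen RNA in Cy3 and -0.033 on the dye-swapped array of the same extracts. A local defect of that array may account for the crowding, but stays open, since the array of pair 3 with collagen RNA in Cy3 had a median of 0.89 over the 3 of these probes it measured. Over all 331 tested probes of these blocks the arrays of pairs 1, 2 and 3 with collagen RNA in Cy3 had medians of 0.33, 0.11 and 0.39, and those with collagen RNA in Cy5 -0.06, -0.10 and -0.03. Loess per print block left 13 probes beyond 1, 11 of them in these blocks.

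The interferon response list leaned upward, with 7 of 8 genes above 0 and a median of 0.19. The averaging of both dye orientations in every pair argues against a dye effect equal on both arrays. The 3 tested explanations stay open. Pair 1 may decide the lean, since the median without it was 0.078 with a standard error of 0.08, against 0.25 and 0.17 without pairs 2 and 3. A dye effect that differs between the arrays of a pair, and is so left after averaging, also cannot be told apart, as the medians were 0.27 with collagen in Cy5 and 0.17 with collagen in Cy3, both above 0, but the lower lay within 2 of its standard errors of 0.13, and over all 11 genes measured with collagen in Cy5 the median was 0.08. More microglial or macrophage RNA cannot be told apart either, as the median of its 6 markers was -0.0022 with a standard error of 0.09. A response of the collagen mice to the immunisation stays open as well, untested beyond the adjusted p of 0.289.

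The 3 pairs allow 4 assignments of collagen and control within pairs, too few for a share under 0.05. All 4 of 4 gave at least as many probes at an unadjusted p under 0.05 as the real one, which gave 135, and the highest other gave 598, with pair 2 turned. That count is several times the real one and points to a structure of the samples or of the arrays. Which of these holds was not tested. Turning pair 2 gave 0 probes past the adjusted test.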
